A study of Mus musculus with 2 samples.

How the data were processed

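The series holds 2 single-cell RNA libraries, 1 from control (Trsp f/f) and 1 from Trsp knockout (Trsp f/f:Mx1-Cre) mouse bone marrow. Per the labels' protocols, mice were given 3 injections of 500 µg of pI-pC on alternating days. The series record gives a time of 7 weeks after birth for the injections, in a wording that leaves the exact age open, and 9 weeks from the last injection to sample preparation. Lineage−, cKit+ cells had been frozen and thawed before loading, per the labels' protocols. How many mice went into each library is not given in the sources used here. Groups were taken from the genotype labels.

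The authors deposited raw UMI counts per gene and cell barcode for 32285 genes, made from 10x Chromium 3′ v3.1 libraries with Cell Ranger 6.1.2 and the mm10 genome, per the file headers and the submitters' processing notes. The annotation release, cell-calling settings and counting by strand are not given in the sources used here. The deposited counts held no barcode with fewer than 500 UMIs. UMIs remove PCR copies of a molecule, so a count is of captured molecules, and the 3′ reads only tell genes apart that differ near their transcript ends. RNA free in the suspension also enters droplets. Mpo gave at least 1 UMI in 92.6% of control and 92.0% of knockout cells of the T, NK or innate lymphoid-like class, which should lack it, at median depths of 10493 and 12706 UMIs, so no share of cells with a UMI is read as expression.

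Barcodes with at least 500 genes and under 10% mitochondrial UMIs were used. Of the control barcodes 31.0% had under 500 genes and 32.9% had 10% or more mitochondrial UMIs, against 31.9% and 33.3% of the knockout barcodes, which left 8192 and 6706. Predicted doublets were scored with Scrublet in scanpy 1.11.5 at an expected rate of 10%. Its automatic threshold marked 215 control cells (2.62%) but only 18 knockout cells (0.27%) and had not worked there. The control threshold, 0.388, was therefore used for both, a choice made after the data were seen, and removed 215 control and 91 knockout cells.

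Cells of both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were ranked within each library, leaving out selenoprotein, sex-linked, mitochondrial and ribosomal protein genes. A graph of 15 neighbours in 30 principal components was clustered with Leiden (leidenalg 0.10.2) at resolution 1, which gave 24 clusters. A cluster took the name of 1 of 16 marker classes if at least 2 of that class's markers were among its 25 leading genes by fold, or failing that by mean marker level. At least 3 markers had to be detected, and no other class could have more markers among the 10 leading genes. Markers and gene lists were fixed before the data were examined, and the naming thresholds were set afterwards. Clusters 2, 5, 10, 13 and 15 stayed unnamed, and of these clusters 5 and 13 are called low-UMI clusters. Cluster 6, led by cell-division genes besides Dntt, was named by mean marker level. Early erythroid-like cells included cluster 23, of 14 cells with few UMIs.

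UMIs were summed per gene over all kept cells and over each class with at least 100 kept cells in each library (7 classes), and divided by the sum of all genes to give counts-per-million (CPM). A gene was measured if it reached 20 CPM in 1 library and 50 UMIs over both. Each sum has an exact Poisson interval, each share an exact binomial (Clopper-Pearson) interval, and each ratio of UMIs an exact conditional binomial interval. A ratio of shares has an approximate normal interval on the log scale. All are at 95% and cover counting error only. A ratio against 0 UMIs is computed with 3 UMIs over the library in place of 0. With 1 library per group no test was made. A list's median log2 ratio (knockout over control) is given as its percentile among 10000 random lists of the same size matched on expression, which describes these 2 libraries only. Under an alternative, a list median was taken as moved when it left the 95% bootstrap interval over the list's genes. A share or gene moved when it left its counting interval, and a count when it changed by more than 1.5-fold. A gene's median over classes moved when it left the range of its class ratios. Of 23 lists fixed before the data were examined, 22 were summarised (sex-linked genes were not). All are given for HSC-like cells. In other classes, selenoproteins, NRF2 targets, mitochondrial transcripts and oxidative phosphorylation are given throughout, and another list only where its median lay outside the central 95% of random lists and was at least 0.3 in size, a rule set after the data were seen. The S phase list in monocyte progenitor-like cells and both lineage programs in multipotent or lymphoid-primed progenitor-like cells were added to these.

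Named genes followed a rule fixed in advance. It took all measured selenoproteins, up to 12 genes highest and 12 lowest among those at least 1.5-fold apart in at least 4 classes, the 6 highest and 6 lowest genes in HSC-like and multipotent or lymphoid-primed progenitor-like cells and 3 and 3 in other classes, and the 2 highest and 2 lowest members of each list, of which examples are given. Genes beyond it are said to be chosen after their values were seen. Genes at least 1.5-fold apart in every class are named, those beyond the 12 after their values were seen, except that 1 lower gene is counted but not reported here. Coordinates and selenocysteine codons are from the GENCODE M21 annotation of the same genome assembly. The last 300 nt of each gene's longest transcript were compared with all annotated transcripts on the same strand with BLAST+ 2.17.0. A copy was a match of at least 100 nt at 95% identity.

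The set of 5 selenoprotein genes compared per cell, and its threshold (the 5th percentile of thinned control cells), were chosen after the data were seen.

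The sums and lists were tested on simulated Poisson counts, drawn for both libraries from a shared set of gene levels apart from the planted differences. These counts held no variation between cells, mice or libraries, so the test checks the calculation only. All planted genes with 2-fold or 4-fold differences that were above the floor were recovered at 1.5-fold or more, and 0% of unchanged genes were. Intervals covered the true ratio for 94.6% of 5866 genes over all kept cells and 95.1% of 6273 genes in HSC-like cells, and a list planted at 1.5-fold stood at percentile 100 in both.

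Alternatives planned in advance were at least 1000 genes with under 5% mitochondrial UMIs, predicted doublets kept, Leiden resolutions of 0.5 and 2.0, class labels from the 15 nearest control cells, median-of-ratios size factors, a floor of 100 CPM, no floor except 10 UMIs, cells thinned to 5591 UMIs, the mean over cells, and equal weight to every class. A doublet score of 0.25, shares and selenoproteins without the low-UMI clusters, and clusters or the whole class without marker genes were added after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.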

Results

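Single-cell RNA sequencing was done on Lineage−, cKit+ bone marrow cells, the fraction that holds hematopoietic stem cells (HSCs) and their early progeny, from femora and tibiae of C57BL/6 mice. The control library came from Trsp f/f marrow and the knockout library from Trsp f/f:Mx1-Cre marrow, in which the interferon-inducible Mx1-Cre deletes Trsp, the gene of the selenocysteine tRNA. Both genotypes had received pI-pC, a double-stranded RNA that induces Mx1-Cre. There was 1 library per genotype, so no difference below has a replicate check or a test, and the intervals given are exact 95% intervals that cover counting error only. The control file held 14372 barcodes with 184683653 unique molecular identifiers (UMIs), and the knockout file held 11556 barcodes with 152092210 UMIs. After filtering, 7977 control cells with a median of 20302 UMIs and 6615 knockout cells with a median of 20692 UMIs were kept. Mitochondrial transcripts made up a median of 3.77% of UMIs in kept control cells and 4.62% in kept knockout cells.

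Selenoprotein mRNAs, which encode proteins that contain selenocysteine, were the closest available check of the genotype labels, since Trsp itself was not analysed here. Of the 24 listed selenoprotein genes, 14 were above the expression floor, 8 of these were at least 1.5-fold lower in the knockout library, and 0 were at least 1.5-fold higher. Selenoh (ENSMUSG00000076437, mm10 chromosome 2, 84669215 to 84670770) stood at 303 counts-per-million (CPM, UMIs scaled to the library total) in control cells (300.2 to 306) and 29.7 in knockout cells (28.8 to 30.6), a 10.2-fold lower level. Gpx1, a cytosolic glutathione peroxidase (ENSMUSG00000063856, chromosome 9, 108338903 to 108340343), stood at 1506 and 252 CPM, 5.97-fold lower. Gpx4, the glutathione peroxidase that reduces lipid hydroperoxides (ENSMUSG00000075706, chromosome 10, 80047166 to 80056439), stood at 396 and 126 CPM, 3.14-fold lower, and Selenow was 6.67-fold lower.

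The log2 ratios of knockout over control for the other selenoproteins ranged from strongly negative values to values near 0. The ratio was −1.91 for Selenom, −1.74 for Selenop, −0.73 for Selenof, −0.69 for Selenot, −0.44 for Selenok, −0.44 for Msrb1 and −0.14 for Selenos. It was 0.23 for Selenoi (0.16 to 0.30) and 0.11 for Txnrd1, the cytosolic thioredoxin reductase (0.07 to 0.15), while the interval for Sephs2 spanned 0 (−0.01 to 0.08). The median over the list was −0.71, at percentile 0 of 10000 random lists of the same size matched on expression. Of the 10 listed genes below the floor, Gpx3 (587 and 47 UMIs, −3.39), Selenon (−0.98) and Txnrd3 (−0.43) were lower, Txnrd2 (2557 and 2585 UMIs, 0.27) and Selenoo (0.16) were higher, and the intervals of Dio2 and Gpx2 spanned 0. Dio1, Dio3 and Selenov had 0 UMIs in both libraries.

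**Figure D1:**
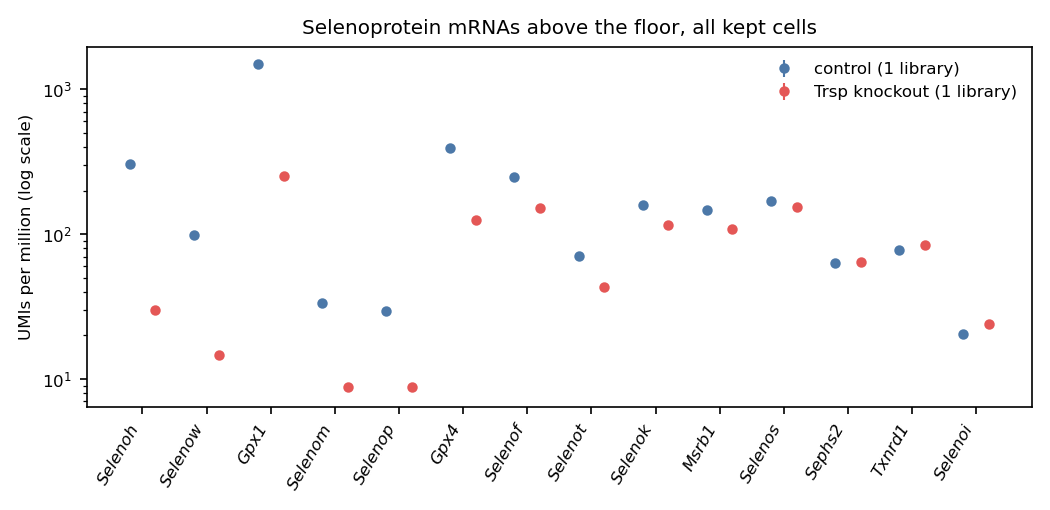
Level of each selenoprotein mRNA above the expression floor, in CPM on a log scale, summed over kept cells of the control library (blue) and the Trsp knockout library (red). Bars are exact 95% Poisson intervals and are smaller than most points; Selenoh, Selenow, Gpx1, Selenom, Selenop and Gpx4 lie lower in the knockout library by 3.14-fold or more.

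The same direction was present within each of the 7 compared cell classes, which had at least 100 kept cells per library. The selenoprotein median ranged from −0.55 in multipotent or lymphoid-primed progenitor-like cells to −0.75 in HSC-like cells. In HSC-like cells Selenow was 8.64-fold lower, Selenoh 7.94-fold, Gpx1 5.10-fold and Gpx4 3.39-fold. The sum of Gpx1, Gpx4, Selenow, Selenoh and Selenop, a set of 5 genes chosen after their values were seen, was also compared per cell after each cell was thinned to 5591 UMIs. The threshold of 5 UMIs was the 5th percentile of the thinned control cells, so the control share is set by that choice. At least 5 UMIs of this set were found in 96.0% of 7673 control cells (95.5 to 96.4) and 10.7% of 5459 knockout cells (9.87 to 11.5). Among HSC-like cells these shares were 86.8% and 3.58%. Without thinning the shares were 97.2% and 65.4% of all kept cells and 97.7% and 34.4% of HSC-like cells. Thinning left out 304 control and 1156 knockout cells with fewer UMIs. Mature B or plasma-like cells, which should be outside a Lineage− sort, stood apart, with a log2 ratio of the summed set of −0.58 in 64 control and 36 knockout cells against −1.87 to −2.59 in the other named classes.

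The shares of the progenitor classes were compared next, because the series title names cell fate. Neutrophil progenitor-like cells made up 19.5% of kept control cells (18.7 to 20.4) and 12.3% of kept knockout cells (11.5 to 13.1), and monocyte progenitor-like cells made up 26.5% and 20.4%. Multipotent or lymphoid-primed progenitor-like cells, marked by Flt3 and Dntt, made up 11.1% (10.4 to 11.8) of control and 13.7% (12.9 to 14.6) of knockout cells. Early erythroid-like cells made up 1.0% (80 cells) and 1.72% (114 cells). HSC-like cells made up 9.70% (9.06 to 10.4) and 8.53% (7.86 to 9.23). Basophil or mast-like cells made up 6.52% and 4.76%, dendritic cell-like cells 2.32% and 2.09%, maturing neutrophil-like cells 1.94% and 2.10% (a direction that turned at other Leiden resolutions, with intervals of the main values that overlapped), eosinophil-like cells 1.68% and 1.16%, mature B or plasma-like cells 0.80% and 0.54%, and T, NK or innate lymphoid-like cells 0.68% and 0.38%. Megakaryocyte progenitor-like cells numbered 30 and 7.

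All of these shares depended in value on 2 unnamed clusters of few UMIs, clusters 5 and 13, which together held 2.13% of control and 19.5% of knockout cells. Rpgrip1 led both clusters, at 100.1 CPM in their control and 98.0 CPM in their knockout cells, against 26.6 and 29.9 CPM in the other kept cells. The control value is limited, since the 8 control cells of cluster 13 had a median of 22396.5 UMIs. They gave 282057 UMIs, against 227614 from the 162 control cells of cluster 5. Their leading genes also included Gm10076 and Hist1h2ap, which were higher in the knockout library in every compared class, so their sizes are not read as the abundance of a cell type. Outside these 2 clusters the log2 ratio of shares was −0.38 for neutrophil progenitor-like cells, −0.10 for monocyte progenitor-like cells, 0.59 for multipotent or lymphoid-primed progenitor-like cells, 1.06 for early erythroid-like cells and 0.10 for HSC-like cells, the last with its direction turned. With class labels taken from the nearest control cells, the log2 ratio was 0.06 for monocyte progenitor-like cells, also turned, −0.62 for neutrophil progenitor-like cells and 0.22 for multipotent or lymphoid-primed progenitor-like cells. At a Leiden resolution of 0.5 the log2 ratio of early erythroid-like cells was 0.02. The clusters left without a name held 10.0% and 8.13% (cluster 2), 3.59% and 2.75% (cluster 10), and 2.08% and 1.80% (cluster 15) of control and knockout cells.

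**Figure D2:**
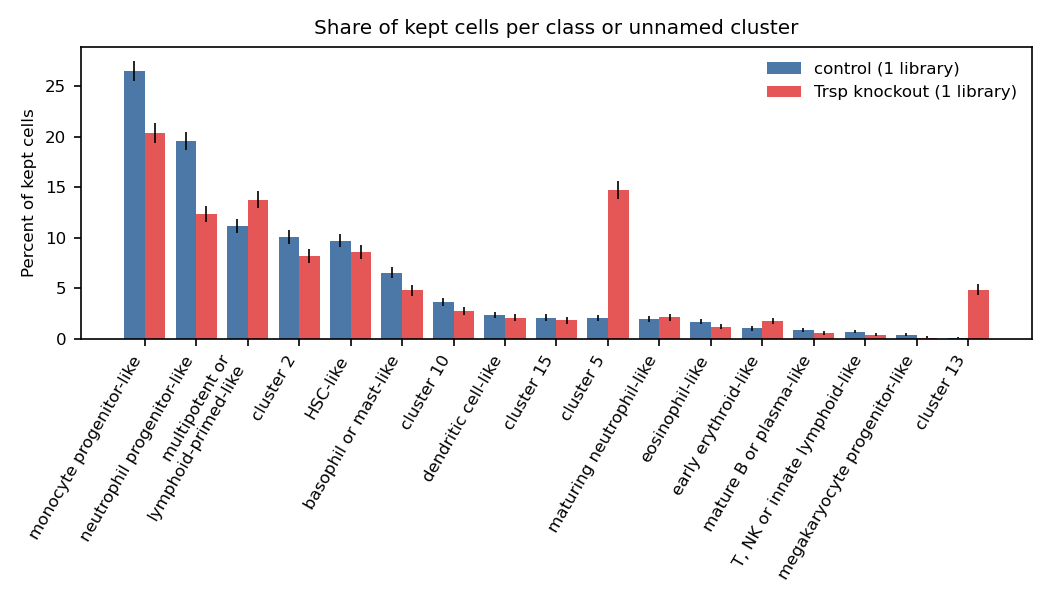
Percent of kept cells of each library in each named class or unnamed cluster, with exact 95% binomial intervals as error bars (control blue, Trsp knockout red, 1 library each). The shares of neutrophil and monocyte progenitor-like cells are lower in the knockout library, and clusters 5 and 13, of few UMIs, together hold 19.5% of its cells.

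Within HSC-like cells, which the title also names, the list median of mitochondrially encoded transcripts was above that of random lists, and the medians of the S phase and type I interferon lists were below. The comparison rested on 774 control and 564 knockout cells, with 9037281 and 7574454 UMIs. The median log2 ratio of the 13 mitochondrially encoded transcripts was 0.28 (percentile 100), with mt-Co1 at 0.56 and mt-Nd4l at 0.44, while mt-Nd2 was at −0.14. This median was 0.11 with a stricter barcode filter. The S phase list had a median of −0.14 over 20 genes (percentile 0), with the replication helicase subunit Mcm7 at −0.43 and Gins2 at −0.27 (−0.58 to 0.04), while 0 of its genes were at least 1.5-fold lower and Clspn was at 0.39. The direction of this list turned with the stricter filter, to 0.04. The type I interferon list had a median of −0.18 over 12 genes (percentile 0.1), with Isg15 at −0.59 (−0.93 to −0.26) and Rtp4 at −0.46, which ranged from −0.76 to −0.21 over the alternatives.

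Among myeloid program genes in HSC-like cells, Ms4a3 and the transcriptional repressor gene Gfi1 were both at −0.54. Their list had a median of −0.19 over 16 genes (percentile 0.01). This median depended on the choices made, from −0.2071 to −0.0095 over the alternatives, with the value nearest 0 at a floor of 100 CPM and with no floor except 10 UMIs. With predicted doublets kept, Gfi1 was at −0.29 and Ms4a3 at 0.05. Beside this stands the background of free RNA, since Mpo, a granule enzyme of neutrophil progenitors, was found at 523 CPM in T, NK or innate lymphoid-like control cells and 188 in knockout ones. The oxidative phosphorylation list, which is encoded in the nucleus, had a median of −0.09 over 20 genes (percentile 2.15), with cytochrome c (Cycs) at −0.35 and Sdhb at −0.34. The G2 and M phase list had a median of 0.21 over only 9 genes, with Ccnb2 at 0.56, Mki67 at 0.49 and Cks2 at −0.22, and the median turned negative under 4 of the alternatives.

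Single genes stood further apart in HSC-like cells than these lists. Adgre5, an adhesion receptor also known as CD97, had 99 control and 312 knockout UMIs (log2 ratio 1.91, 1.58 to 2.25). It was also higher in multipotent or lymphoid-primed progenitor-like cells, at 1.44 to 1.74 over the alternatives. In HSC-like cells the transcription factor Hivep2 had 62 and 167 UMIs (1.68). H2-Eb1, a class II histocompatibility gene and a marker of the dendritic cell class, had 68 and 155 (1.44). Selp, which encodes P-selectin and belongs to the HSC aging list, was 2.36-fold higher, at 23.8 and 56.1 CPM. Txnip, which encodes thioredoxin-interacting protein, was 1.74-fold higher, at 226 and 393 CPM, and was also higher in the other compared classes. Hlf was at 0.30 and Nr4a1 at −0.48. Hist1h2ap was 8.59-fold higher, Gm10076 (log2 ratio 2.54), Hist1h2ae (1.56) and the glycolytic gene Eno1 (1.27) were also higher, and Ctse was lower (−3.17), as in the other classes described below.

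The remaining lists lay within the central 95% of random lists in HSC-like cells. Medians were 0.11 for HSC aging (3 genes), 0.06 for HSC self-renewal and quiescence (14 genes), 0.11 for the lymphoid program (7 genes), 0.05 for the selenocysteine machinery (6 genes), 0.04 for NRF2 targets (14 genes) and 0.03 for the integrated stress response (12 genes), in which Ddit4 alone was at least 1.5-fold higher. Medians were −0.03 for antioxidant enzymes without selenium (18 genes), −0.06 for ferroptosis (13 genes), −0.09 for iron and heme (11 genes), −0.04 for immediate early genes (15 genes), −0.01 for p53 targets (8 genes) and −0.04 for the megakaryocyte program (5 genes). The unfolded protein response (0.0021), cholesterol synthesis (0.0084) and glycolysis (0.0032) lists had medians near 0.

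For targets of NRF2, the transcription factor of the oxidative stress response, the list medians were above those of random lists in the 6 compared classes other than HSC-like cells. Not every target was higher in each of these classes. In monocyte progenitor-like cells 9 of 14 measured targets were at least 1.5-fold higher (median log2 ratio 0.69), in neutrophil progenitor-like cells 8 of 15 (0.67), and in multipotent or lymphoid-primed progenitor-like cells 5 of 14 (0.47). The counts were 5 of 15 in maturing neutrophil-like cells (0.46), 3 of 12 in dendritic cell-like cells (0.39), 6 of 14 in basophil or mast-like cells (0.35), and 0 of 14 in HSC-like cells, where the highest were the ferritin light chain Ftl1 at 0.33 and Abcc1 at 0.25. All 6 medians lay at percentile 99.98 or above of their random lists, and that of HSC-like cells lay at 81.2. The difference between classes was not tested. At a Leiden resolution of 2.0 the median in HSC-like cells was 0.29, and at a resolution of 0.5 the median in multipotent or lymphoid-primed progenitor-like cells was 0.06.

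Over all kept cells, Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, was 2.66-fold higher (83.9 and 223 CPM), and Ftl1 was 2.39-fold higher (479 and 1148 CPM). In monocyte progenitor-like cells Gclm was at 1.99 and Ftl1 at 1.49 on the log2 scale, and Pir was at 3.89 with 87 control and 1019 knockout UMIs. Slc7a11, the cystine transporter that supplies glutathione synthesis, was at 3.66 in neutrophil progenitor-like cells (113 and 949 UMIs) and 1.79 in maturing neutrophil-like cells, in which the heme pathway reductase Blvrb was at 1.28. Glutathione reductase (Gsr) was at 1.15 in dendritic cell-like cells. Each of the 7 listed targets below the floor over all kept cells had more CPM in the knockout library, among them 3 chosen after their values were seen, Nqo1 with 204 and 1635 UMIs, Srxn1 with 342 and 1758, and Hmox1 with 142 and 699. Catalase (Cat), an antioxidant enzyme without selenium, was 2.04-fold higher over all kept cells, while the median of its list of 18 genes was −0.07 (percentile 0.84).

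**Figure D3:**
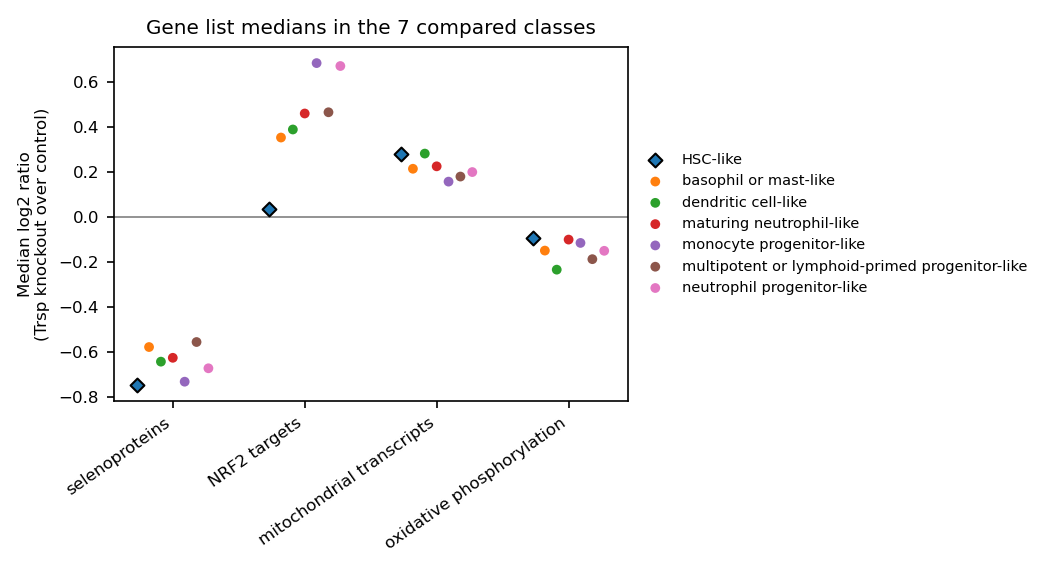
Median log2 ratio of knockout over control for 4 gene lists in the 7 compared classes, with 1 point per class and HSC-like cells drawn as a diamond. Selenoprotein medians lie between −0.75 and −0.55, and the median of NRF2 targets is 0.04 in HSC-like cells and 0.35 to 0.69 in the other classes.

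List medians of mitochondrially encoded transcripts were above 0 in the 7 compared classes, and those of nuclear oxidative phosphorylation transcripts were below 0. Single genes differed, and mt-Nd2, for example, was at −0.22 in multipotent or lymphoid-primed progenitor-like cells and 0.07 in dendritic cell-like cells. The medians of the former ranged from 0.16 in monocyte progenitor-like cells to 0.28 in HSC-like and dendritic cell-like cells, and those of the latter from −0.09 in HSC-like cells to −0.23 in dendritic cell-like cells. The oxidative phosphorylation median in maturing neutrophil-like cells, −0.10, lay within the central 95% of random lists. Over all kept cells the medians were 0.17 and −0.13, with mt-Co1 at 0.47 and Cycs at −0.43. These mitochondrial medians stand beside the higher mitochondrial share of kept knockout cells (4.62% against 3.77%) and depended on the barcode filter. With at least 1000 genes and under 5% mitochondrial UMIs they were 0.04 in monocyte progenitor-like, 0.07 in neutrophil progenitor-like, 0.07 in multipotent or lymphoid-primed progenitor-like, 0.11 in HSC-like and 0.14 in basophil or mast-like cells, while that of dendritic cell-like cells was 0.28. This filter cuts on mitochondrial UMIs themselves, so smaller medians under it do not tell where the difference comes from. Median-of-ratios size factors gave mitochondrial medians of 0.07 in monocyte progenitor-like and 0.08 in neutrophil progenitor-like cells. Relative to total UMIs, the median over all measured genes was 0.12 in neutrophil progenitor-like cells, 0.11 in maturing neutrophil-like cells and 0.08 over all kept cells.

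In multipotent or lymphoid-primed progenitor-like cells, the median of the lymphoid program was above 0 and that of the myeloid program below 0, and both were nearer to 0 without genes that mark or lead clusters. Of 11 measured lymphoid genes 4 were at least 1.5-fold higher (median 0.44), with Rag1, which encodes a subunit of the V(D)J recombinase, at 80 and 445 UMIs (log2 ratio 2.30) and the B-lineage transcription factor Ebf1 at 175 and 900 UMIs (2.18). Of 17 myeloid genes 2 were at least 1.5-fold lower (median −0.31), with the granule protease Ctsg at −0.89 and Ms4a3 at −0.76. Ctsg was below 0 in every compared class, for example at −0.87 in dendritic cell-like and −0.56 in basophil or mast-like cells. The lower background of free Mpo RNA in the knockout library, given above, stands beside these myeloid values too. Ebf1 and other lymphoid genes define part of the multipotent or lymphoid-primed progenitor-like class, which joined cluster 6 (539 control and 518 knockout cells, led by Dntt and cell-division genes) and cluster 8 (347 and 390 cells). Without marker and cluster-leading genes, the whole class had a lymphoid median of 0.29 over 3 genes and a myeloid median of −0.0023 over 8 genes. By cluster, the lymphoid median was 0.32 over 2 genes in cluster 6 and 0.29 over 4 genes in cluster 8, and the myeloid median was −0.08 over 9 genes and −0.29 over 9 genes. Over all kept cells the lymphoid median was 0.32 (7 genes), with Dntt at 0.66 and Flt3 at 0.48, and Ctsg was at −0.62 and Elane at −0.46.

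Genes and lists that stood apart in the remaining classes were not tested for a difference between classes. In dendritic cell-like cells the cholesterol synthesis list had a median of −0.44, with 6 of 15 genes at least 1.5-fold lower, among them Idi1 at −1.38 and Sqle at −1.01, while Hpgd, a prostaglandin-degrading enzyme, had 19 and 98 UMIs (2.56). The cholesterol synthesis median was −0.22 with predicted doublets kept. In basophil or mast-like cells the unfolded protein response list had a median of −0.34, with Sdf2l1 at −0.71 (−0.46 in multipotent or lymphoid-primed progenitor-like cells) and Creld2 at −0.61, and Aldh1a1 had 48 and 138 UMIs (2.01). With the stricter barcode filter the unfolded protein response median in that class was −0.10, Sdf2l1 was at −0.24 and Creld2 at −0.20. In neutrophil progenitor-like cells the secondary granule gene Camp had 1262 control and 92 knockout UMIs (−3.19), and Ngp, named after its values were seen, had 552 and 29. Both are markers of the maturing neutrophil class, in which Camp was at 0.02 with 4666 and 5072 UMIs. In maturing neutrophil-like cells Retnlg, also a marker of that class, had 280 and 13 UMIs, and Ncmap had 55 and 0 UMIs. With 3 UMIs put for 0, Ncmap was 19.7-fold lower, and the counting interval of its log2 ratio reached up to −3.95.

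Further list medians of 0.3 or more in size outside the central 95% of random lists were those of the HSC aging list in basophil or mast-like (0.81, 3 genes), monocyte progenitor-like (0.35, 4 genes) and neutrophil progenitor-like cells (0.34, 3 genes), the lymphoid program in maturing neutrophil-like cells (0.51, 5 genes), and the iron and heme list in neutrophil progenitor-like cells (0.31, 14 genes), which shares Ftl1 and Fth1 with the NRF2 targets. With no floor except 10 UMIs the HSC aging median was −0.04 in monocyte progenitor-like cells, turned, and 0.09 in neutrophil progenitor-like cells, where the iron and heme median was 0.20. The antisense gene Gm20658 had 12 control and 1200 knockout UMIs in monocyte progenitor-like cells (log2 ratio 6.99), which is uncertain because the counting was not stated to separate strands. Over all kept cells the heat-shock gene Hspa1a was 2.58-fold lower and the platelet factor gene Pf4 2.25-fold lower. The log2 ratio of Pf4 was −0.41 as a mean over cells, −0.04 in HSC-like cells and 1.14 in basophil or mast-like cells, so its lower sum was not shared by these classes.

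A small set of genes was at least 1.5-fold apart in the same direction in every class in which it passed the floor. Of 5958 genes considered, 15 were higher and 16 lower in the knockout library. The 16 lower genes included the 6 selenoproteins Selenoh, Selenow, Gpx1, Selenop, Gpx4 and Selenof. Ctse, which encodes the aspartic protease cathepsin E (ENSMUSG00000004552, chromosome 1, 131638306 to 131675505), was lower by a median of 14.4-fold over 7 classes. Over all kept cells its log2 ratio was −3.08 (8390 and 830 UMIs), a smaller difference than that of Selenoh (−3.35). Rnaset2a (median log2 ratio −1.46) and Rnaset2b (−1.40), copies of a lysosomal ribonuclease gene on chromosome 17, Rpl9-ps6 (−1.45), the phosphohistidine phosphatase gene Phpt1 (−1.43), Wdr89 (−1.28), Rps27rt (−1.08), Rpl36a-ps1 (−1.07) and Hypk (−0.75) were also lower.

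Among the 15 higher genes, Hist1h2ap (chromosome 13, 21833026 to 21833507) had a median log2 ratio of 3.01 and Gm10076, a non-coding gene on chromosome 14, of 2.51. The histone genes Hist1h4h (1.63), Hist1h2ae (1.60), Hist2h2aa1 (1.23) and Hist1h3f (0.81), the glycolytic enzyme gene Eno1 (1.72), the ribosomal protein gene Rpl35 (1.38), Dynlt1f (1.15), the antisense gene Gm15564 (1.11), the HSP90 co-chaperone gene Ahsa1 (1.04), Dleu2 (1.01), the proteasome ubiquitin receptor gene Adrm1 (1.99-fold), Txnip (0.96) and Adat2 (0.86) were also higher. Among the higher and lower genes together, selenoproteins left out, values for 15 are uncertain. The last 300 nt of their transcripts closely matched another gene, and reads can be divided between the copies. Summed over the counted copies, Eno1 (1.59), Rpl35 (1.24), Dynlt1f (1.22), Adrm1 (8253 against 4917 UMIs), Hist1h2ae (0.82), Rnaset2a and Rnaset2b (both −1.47) were still at least 1.5-fold apart, and the other 8 were not. Gm10076 matched Rpl41, Rnaset2a and Rnaset2b matched each other, and Hist1h2ap, Hist1h4h, Rpl9-ps6 and Rps27rt each matched several genes. Ctse, Phpt1, Wdr89, Ahsa1, Txnip, Adat2, Hypk and Gm15564 had no such match. Hist2h2aa1 was not searched, because the search covered only genes measured over all kept cells. With a floor of 100 CPM, 6 genes were higher and 6 lower.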

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

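The S phase list is given here because it differed in direction between classes, with a median log2 ratio of −0.138 in HSC-like cells and 0.146 in monocyte progenitor-like cells. This difference was not tested, and the HSC-like value turned to 0.0387 with the stricter barcode filter. Mcm7 was lower in both classes, at −0.43 and −0.52, and Rrm1 was at 0.30 in monocyte progenitor-like cells. The other result comes from barcodes left out of the kept cells for holding under 500 genes, which were used only as a reference for the low-UMI clusters. Among these barcodes, mitochondrial transcripts made up 65.5% of the UMIs of 3686 knockout barcodes and 56.5% of those of 4449 control barcodes.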

How the results depend on the processing

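No paired analysis was possible because each genotype had 1 library and no test was made, and there was no replicate to leave out. Values are log2 ratios unless stated, and the cause of each difference was not tested. The selenoprotein median was negative under every alternative run, at −0.79 to −0.44 over all kept cells and down to −1.80 within classes. Of 1818 recomputed values, 14 turned a result that had a direction, and 50 had the other sign for 14 results that had none, because the interval of a share or gene spanned 0 or a median lay within the central 95% of random lists. Moved values not listed below numbered 40 with thinned cells and 39 with size factors. They numbered 35 with the stricter filter, 26 with the mean over cells and fewer elsewhere. The few cells limit the megakaryocyte progenitor-like class (30 and 7 cells) most. The doublet score of 0.25, the shares without low-UMI clusters and the clusters and class without marker genes were chosen after the data were seen.

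With the stricter barcode filter the S phase median in HSC-like cells turned to 0.0387, the G2 and M phase median to −0.0674 and Mki67 to −0.0671. In the same cells the oxidative phosphorylation median was −0.029 and the interferon median −0.2884. Mitochondrial medians were 0.1397, 0.0384 and 0.0688 in basophil or mast-like, monocyte progenitor-like and neutrophil progenitor-like cells, and in basophil or mast-like cells the oxidative phosphorylation median was −0.1264 and the unfolded protein response median −0.0988. Shares moved to 0.3193 for dendritic cell-like (opposite in sign to −0.15), 1.712 for early erythroid-like, −0.1725 for monocyte progenitor-like and 0.5885 for multipotent or lymphoid-primed progenitor-like cells.

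With predicted doublets kept, in HSC-like cells the G2 and M phase median was −0.1089, Mki67 −0.1576 and Ms4a3 0.0473, all turned. The cholesterol synthesis median in dendritic cell-like cells was −0.2235, the oxidative phosphorylation median in multipotent or lymphoid-primed progenitor-like cells −0.1135, and the shares of monocyte progenitor-like and multipotent or lymphoid-primed progenitor-like cells −0.5704 and 0.4973. With the doublet score of 0.25 the first 2 of these were also turned, at −0.1276 and −0.088, the unfolded protein response median in basophil or mast-like cells −0.1068, NRF2 targets and oxidative phosphorylation in multipotent or lymphoid-primed progenitor-like cells 0.0787 and −0.0282, the share of that class 0.4402, and the share of neutrophil progenitor-like cells −0.3308.

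At a Leiden resolution of 0.5, in HSC-like cells the G2 and M phase median turned to −0.0459. In multipotent or lymphoid-primed progenitor-like cells NRF2 targets were at 0.0647 and oxidative phosphorylation at −0.0903, and shares were 0.0212 for early erythroid-like, −0.64 for maturing neutrophil-like (opposite in sign to 0.11) and −0.3457 for neutrophil progenitor-like cells. At 2.0, in HSC-like cells Mki67 turned to −0.0032, NRF2 targets were at 0.2898 and the lymphoid program at 0.0255, and shares were −0.5348 for maturing neutrophil-like (again opposite), −0.4785 for monocyte progenitor-like and −0.4814 for neutrophil progenitor-like cells. With labels from the nearest control cells the share of monocyte progenitor-like cells turned to 0.062.

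Without the low-UMI clusters the share of HSC-like cells turned to 0.0959, that of dendritic cell-like cells, whose interval spanned 0, was 0.1297, and shares were −0.1706 for basophil or mast-like, 1.0635 for early erythroid-like, 0.3953 for maturing neutrophil-like, −0.0977 for monocyte progenitor-like, 0.5879 for multipotent or lymphoid-primed progenitor-like and −0.385 for neutrophil progenitor-like cells. In cluster 8 alone, without marker and leading genes, the lymphoid median was 0.2862, and in the whole multipotent or lymphoid-primed progenitor-like class without these genes the myeloid median was −0.0023.

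With median-of-ratios size factors the oxidative phosphorylation median was −0.2053, −0.1979 and −0.2699 in maturing neutrophil-like, monocyte progenitor-like and neutrophil progenitor-like cells, and the mitochondrial median 0.0748 and 0.0804 in the last 2. With a floor of 100 CPM, 6 genes were higher and 6 lower in every class, of which 5 and 6 were among the 15 and 16, as fewer genes pass this floor, and iron and heme medians were 0.3268 in HSC-like (opposite in sign to −0.09) and 0.5345 in neutrophil progenitor-like cells. With no floor except 10 UMIs, in monocyte progenitor-like cells the HSC aging median turned to −0.0389 and NRF2 targets were at 0.9984. With thinned cells the integrated stress response median in HSC-like cells was 0.1296, and with the mean over cells Txnrd1 turned to −0.0002.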

Other observations

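The tests of class mix, near-identical copies and their sums, linked DNA, a separate cell state, selenoproteins below the floor and genes above both RNA sources were chosen after the results were seen. The test of selenocysteine codon position was written before codon positions were compared but after the ratios were known, and the test of damaged cells was written before its result.

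The mature B or plasma-like class was the named class in which the summed set of 5 selenoprotein mRNAs differed least between the libraries. In this class, led by Igkc and Jchain, Selenow stood at 190 CPM in both libraries (301 and 183 UMIs) and Gpx4 at 241 and 205. Gpx1 was still 2.77-fold lower and Selenoh 4.60-fold lower in the knockout library. At 5591 UMIs per cell, 27.0% of 63 control cells of this class and 25.7% of 35 knockout cells had at least 5 UMIs of the 5-gene set, so the low share was already present in the control library. Without thinning the shares were 96.9% and 88.9%. In early erythroid-like cells the 5-gene set was lower by 3.66-fold, against 6.02-fold in neutrophil progenitor-like cells. These values were looked up after the main results and were not tested.

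The unequal levels of selenoprotein mRNAs went with the place of the selenocysteine codon. The 8 measured genes whose codon lies at least 50 nt before the last exon junction had a median log2 ratio of −1.83 (−3.35 to −0.69), and the 6 others had −0.05 (−0.44 to 0.23), so the first kind was lower in 100% of pairs. With 6 genes below the floor included, the share was 90.9% of pairs over 20 genes, and Txnrd2 goes against it, with its codon 83 nt before the last junction and a ratio of 0.27. Within classes this held for 88.9% of pairs in HSC-like cells and 100% in the other 6. A different mix of cell classes is excluded as the whole cause, because the highest class median was −0.5548, and nonsense-mediated decay of transcripts in which the codon is read as a stop is a candidate explanation that 1 library per genotype leaves as a hypothesis.

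Near-identical gene copies may account for some genes apart in every class, but division among counted copies does not account for all. Of 24 non-selenoprotein genes that were searched, 62.5% had a near-identical transcript end elsewhere. Random sets had a median of 4.17% and an upper bound of the central 95% of 16.7%. After summing each family, 8 of the 15 genes with a match were within 1.5-fold, although summing with an abundant copy also dilutes a real difference. Among these 8, Dleu2 matched differently named genes such as Tmem131l and Ube2e1, so its sum (27720 and 28005 UMIs) need not be that of copies. The sums of the other 7 of the 15 stayed at least 1.5-fold apart. Division among counted copies is excluded as the whole cause for Eno1, Rpl35, Dynlt1f, Adrm1, Rnaset2a and Rnaset2b. It stays open for Hist1h2ae. The Hist1h2ae copies Hist1h2ab and Hist1h2ac also match Hist1h2ap, whose wider family sum was at 0.39. Reads left uncounted because they match several places stay open for all 7. For the 9 genes without a match, which include Ctse, Phpt1, Wdr89 and Txnip, no annotated copy of the searched transcript end was found. Their other transcript ends and copies outside the annotation were not searched. A single stretch of linked DNA is excluded as the whole cause, since the 10 Mb window with the most of these genes held 16.67% of them and they lay on 12 chromosomes, while sequence differences at several loci between the mice and an effect of genotype may explain the 9 and the 7 genes and were not tested.

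The 2 low-UMI clusters resembled the knockout library's own mixture of RNA slightly more than any named class. Their summed profile correlated across 6029 genes with that of the left-out knockout barcodes of under 500 genes at Pearson r = 0.967. This was only slightly above the best named class (0.954, monocyte progenitor-like), and r was 0.983 with all other kept knockout cells. Genes are not independent replicates. Pooled kept cells gave the highest r, so r cannot tell damage or free RNA from intact cells of several classes with few UMIs. The rule for a cell type or state of its own counted genes at least 4-fold above every named class of at least 25 cells. Fewer than 3 would go against such a state, and 0 were found. A first test against the 7 compared classes gave 5, Prg2, Jchain, Igkc, Hbb-bs and Mt2, which lead named classes too small to be compared. Such a state stays open, because 4 of 6193 genes were at least 2-fold above both the left-out barcodes and the other kept cells. These were Rpgrip1, Slc39a1, Notch2 and Abhd2. Rpgrip1 was so in the control library too, where 8 cells of cluster 13 at usual depth gave most UMIs of the 2 clusters. Mitochondrial UMIs made up 4.95% of the pooled UMIs of the knockout cells in these clusters and 65.5% in the left-out barcodes. This contrast was set by the filter and cannot weigh damage, since only kept barcodes had to stay below its mitochondrial limit. The median was 6.68% in the 972 knockout cells of cluster 5. It was 4.62% in kept knockout cells and 2.53% in the control cells of cluster 5. Damaged cells or free RNA stay a candidate explanation only, and handling and genotype cannot be separated with 1 library each.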
